A study of Rattus norvegicus with 6 samples.

How the data were processed

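The measurements came from 6 single-channel Affymetrix expression arrays, each hybridized with 1 sample of biotin-labelled RNA. The samples were heart muscle cells isolated from newborn Wistar rats 1 to 2 days old. Per the labels' protocols, the hearts were digested with pancreatin and collagenase, and the myocytes were separated from fibroblasts on a Percoll density gradient. The labels name 3 groups of 2 arrays, which are untreated control cells, cells given phenylephrine at 50 µmol/l, and cells stretched biaxially to 112% for 24 h. Phenylephrine is an agonist of the α1-adrenergic receptor and a standard hypertrophic stimulus for cultured myocytes. The stretched cells grew on a collagen-coated silicone membrane for 36 h and were kept without serum for 24 h before the stretch, per the labels. The duration of the phenylephrine treatment and the growth surface of the control and phenylephrine cells are not given in the sources used here. The same holds for the plating time and the period without serum of the control and phenylephrine cells.

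Per the labels' protocols, RNA of more than 1 cell preparation was combined and then amplified by in vitro transcription. Nothing in the labels says that the 2 arrays of a group came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

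The deposited table gives 1 value per probe set and array. Its values were taken as log2 expression because they ran from about 6 to 15, the range of log2 scanner signals. The probe set summary, background correction and normalization that the authors used are not given in the sources used here, and no detection calls were used. The array medians of the deposited log2 values differed by 0.038, less than the limit of 0.3 set before the data were examined, so the authors' normalization was kept. Normalization of the whole array assumes that most probe sets did not change, and a change shared by most probe sets would not be visible. Dim and very bright probe sets give compressed folds. For arrays, the number of arrays limits the precision.

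The table held 31099 probe sets, of which 57 array controls were left out and 31042 were tested. Genes were taken from the platform annotation of 2016. Of the tested probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none. Entrez identifiers of 20764 probe sets matched the rat RefSeq table of assembly GRCr8, and 0 symbols needed an update. Probe sets with several symbols were tested but not named. A gene was represented by its probe set with the highest mean over the 6 arrays. No genome coordinates were used.

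A model with 1 mean per group was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend. The 3 contrasts were stretch against control, phenylephrine against control, and stretch against phenylephrine. Tests were two-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. The fit had 3 residual degrees of freedom, and the empirical Bayes prior added 4.8. All adjusted p-values of genes are from this limma fit. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so none was used.

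Gene lists were fixed before the data were examined: 24 lists of pathways and processes and 9 lists of cell type markers. Of 757 listed genes, 677 were found. Each list was tested with camera in limma, with the preset correlation of 0.01 between genes and adjustment over the 33 lists of a comparison. Camera was also run with a correlation estimated for each list, and none of the 20, 18 and 10 list calls of the 3 comparisons held with it. The limma test fry was run as another alternative. For each list the number of members past the threshold is given over all probe sets tested, and adjusted over the list alone where stated.

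Genes named in the text follow a rule fixed before the data were examined. In each comparison these are the 10 largest rises and 10 largest falls past the threshold with no overlap between the arrays of both groups, fewer where fewer qualified. A panel of 14 hypertrophy and stress genes was added. From each list up to 4 members past the threshold with the largest changes were named, or else the member with the largest change, as a value. Genes outside this rule are marked as chosen after their values were seen.

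The fit was tested on simulated data with the real means of the 31042 probe sets and 2 models of their variances. With the fitted variance of each probe set, 10.1%, 7.1% and 7.3% of calls were false for stretch against control, phenylephrine against control and stretch against phenylephrine, above the nominal level. The recovered shares were 67.2%, 74.6% and 65.7% for changes of 0.5 log2, 100%, 98.5% and 100% for 1 log2, and 100% for 2 log2. The other model was added after an excess of false calls had been seen. It draws the variances from the prior that limma fitted, which is limma's own assumption, and then 2.4%, 2.7% and 4% of calls were false. The recovered shares were then 49.3%, 23.9% and 53.7% for 0.5 log2, 92.5%, 92.5% and 95.5% for 1 log2, and 100% for 2 log2. The true share of false calls may therefore lie above 5%. With either model a gene list shifted by 0.5 log2 was called in each comparison and 0 of the other lists were. The simulated probe sets varied independently, while the correlation estimated from the data was 0.278 for the ATF4 list and 0.355 for the NRF2 list. The simulation therefore does not show how often camera calls lists of correlated genes falsely. Alternatives were another normalization between arrays, a filter on dim probe sets, other spread models, fits of 2 groups, a term for the replicate number, the omission of each array, other thresholds, other tests of lists, and the mean of a gene's probe sets. The effect of the control arrays shared by both treatments on the correlation was simulated in 100 data sets without any effect. After the data had been seen, both treatments were also compared with 1 separate control array each, in a fit with 2 residual degrees of freedom.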

Results

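Gene expression was measured with 6 arrays in cultured heart muscle cells of newborn rats, 2 arrays each of untreated control cells, cells given phenylephrine, and cells under biaxial stretch. The series is about expression patterns particular to stretched myocytes, and phenylephrine stands beside stretch as a chemical growth stimulus. Values are log2 signals as deposited, changes are differences of group means with the standard error (SE) of the limma fit, and n = 2 arrays per group throughout.

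The 6 arrays were alike in their medians, which lay between 8.30 and 8.33 log2. They were less alike in the width of their distributions, which the check of medians does not see. The interquartile range on the control, phenylephrine and stretch arrays was 1.91, 1.89 and 1.92 log2 for replicate 1. For replicate 2 it was 1.82, 1.70 and 1.80. The correlation of arrays across probe sets lay between 0.984 and 0.995, and probe sets are not independent replicates. Phenylephrine replicate 2 stood apart in its spike-in hybridization controls, whose median was 9.31 log2 against 10.1 to 10.4 in the other 5 arrays. The probe set for 5S ribosomal RNA was also lowest on that array, at 9.37 against 10.6 to 11.8. It was 11.4 and 11.8 on the control arrays, 10.7 and 11.1 on the stretch arrays and 10.6 on phenylephrine replicate 1. All treated arrays thus lay below both controls. The difference between 3′ and 5′ probe sets, a measure of RNA integrity, set the phenylephrine arrays apart in both directions. It was 0.248 and 0.304 log2 for GAPDH on these arrays, against 0.356 to 0.587 on the other 4, and 0.97 and 1.04 for beta-actin, against 1.10 to 1.41. For hexokinase it was 1.65 and 1.88, against 1.29 to 1.49.

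Stretch against control was the comparison for the mechanical stimulus. Among named genes, the largest rises were those of Mt2A, Hspa1a, Gdf15 and Hmox1, which take part in stress responses. Mt2A, a metal-binding metallothionein (probe set 1388271_at), rose 7.79-fold, from 11.11 ± 0.01 to 14.07 ± 0.17 log2 (mean ± SD, n = 2; adjusted p = 0.00074). Hspa1a, which encodes the inducible chaperone Hsp70 (probe set 1370912_at), rose 7.22-fold (2.85 ± 0.10 log2, SE; adjusted p = 4.31e-05). The gene has a near-identical copy, so the probe set may read both. Gdf15, a secreted stress cytokine of the TGF-β family (probe set 1370153_at), rose 7.11-fold (2.83 ± 0.10; adjusted p = 4.31e-05). Hmox1, the heme-degrading enzyme heme oxygenase 1 (probe set 1370080_at), rose 5.78-fold (2.53 ± 0.14; adjusted p = 0.000675). The largest fall was that of Pla2g2a, a secreted phospholipase A2 (probe set 1368128_at), which was 4.02-fold lower (-2.01 ± 0.12; adjusted p = 0.000803).

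The other large rises with stretch included Mllt11 (2.11 ± 0.11), Cks2, a binding partner of cyclin-dependent kinases (1.82 ± 0.12), and the growth arrest gene Gadd45g (1.79 ± 0.12). Trib3, a pseudokinase of the stress response, rose by 1.63 ± 0.09, the asparagine synthetase gene Asns by 1.63 ± 0.15, and Lmcd1, a LIM domain cofactor, by 1.51 ± 0.14. Only 9 named genes met the rule for falls. After Pla2g2a these were Lcn2, an iron-binding lipocalin (-1.41 ± 0.12), the connexin gene Gja5 (-0.99 ± 0.13), the complement gene C3 (-0.70 ± 0.08) and the ephrin receptor gene Epha4 (-0.66 ± 0.07). Enpp2 (-0.54 ± 0.07), Slc25a34 (-0.52 ± 0.07), Abi3bp (-0.46 ± 0.06) and the chemokine gene Cxcl2 (-0.41 ± 0.06) fell less. In all, 107 of 31042 probe sets changed in limma, 95 up and 12 down, for 70 named genes up and 12 down. Changes of at least 2-fold made up 48 of these. In a fit with a term for the replicate number 1028 passed, 719 up and 309 down.

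**Figure D1:**
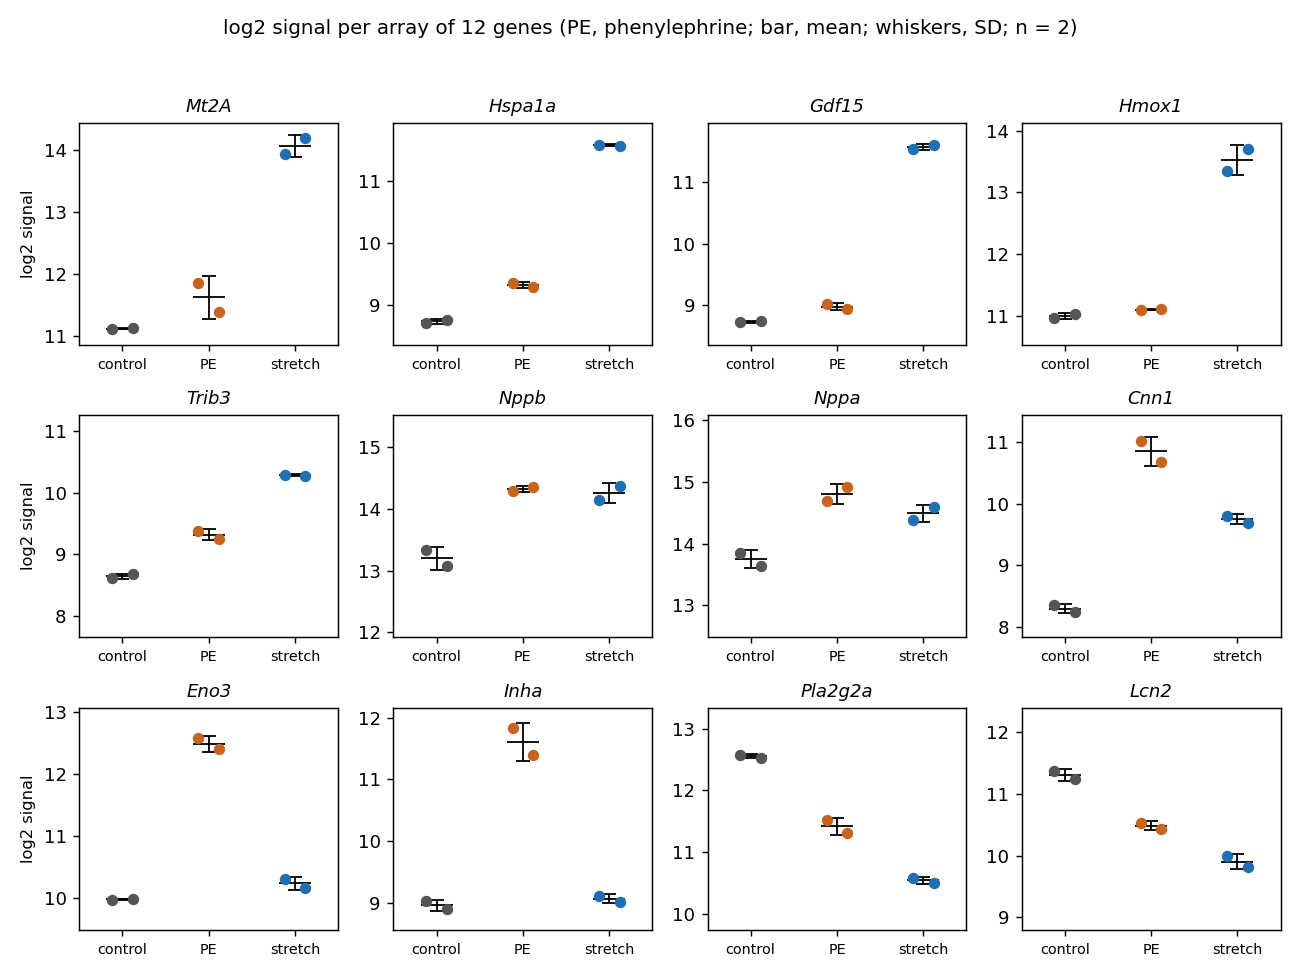
log2 signal of 12 genes on each of the 6 arrays (points), with the group mean (bar) and SD (whiskers) of 2 arrays. Each panel spans 3.6 log2. Both stretch arrays lie above all 4 other arrays for Mt2A, Hspa1a, Gdf15, Hmox1 and Trib3, and both phenylephrine arrays lie above the others for Eno3 and Inha.

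Among genes of the amino acid stress response driven by the transcription factor ATF4, 12 of 29 measured members rose with stretch and 0 fell. The number that rose was 24 adjusted over the list alone. The members include Gdf15, Trib3, Asns and Mthfd2, a mitochondrial folate enzyme (1.21 ± 0.11; adjusted p = 0.0048). The median change of the list was 0.73 log2, with camera adjusted p = 3.27e-46 and adjusted p = 0.181 with an estimated correlation. Of 18 antioxidant genes driven by NRF2, 3 rose and 0 fell, or 13 adjusted over the list alone. These were Hmox1, the sulfiredoxin gene Srxn1 (1.46 ± 0.12; adjusted p = 0.00308) and the thioredoxin reductase gene Txnrd1 (0.79 ± 0.11; adjusted p = 0.0383). The list median was 0.45, with camera adjusted p = 5.61e-17 and adjusted p = 0.181 with an estimated correlation. Of 16 heat shock genes, 1 rose, Hspa1a, also 1 adjusted over the list alone, and the list median was 0.21 with camera adjusted p = 3.71e-07 and adjusted p = 0.231 with an estimated correlation. Of 20 chaperone genes of the endoplasmic reticulum, 0 passed in limma, and 0 had an unadjusted p under 0.05, with a median of 0.086 and camera adjusted p = 0.0733. The member with the largest value was Dnajb9 (0.27 ± 0.19).

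In the list of hypertrophy and fetal genes, 2 of 16 members rose with stretch, and 12 did so adjusted over the list alone. Fhl1, a LIM domain protein, rose by 1.19 ± 0.11 (adjusted p = 0.00678). Nppb, which encodes brain natriuretic peptide, rose by 1.05 ± 0.12 (adjusted p = 0.0154). All 16 members had a change above 0, with a median of 0.48 and camera adjusted p = 1.98e-16 and adjusted p = 0.181 with an estimated correlation. The atrial natriuretic peptide gene Nppa had 0.74 ± 0.12 (adjusted p = 0.0717) and the skeletal actin gene Acta1 0.71 ± 0.11 (adjusted p = 0.0593), neither past the threshold. Among other genes of the panel, those that did not pass included the myosin genes Myh7 (0.10 ± 0.11) and Myh6 (-0.16 ± 0.10) and the calcium pump gene Atp2a2 (0.03 ± 0.10). Rcan1 (0.46 ± 0.14), Ankrd1 (0.15 ± 0.11), Fgf21 (0.09 ± 0.07), Fos (0.45 ± 0.21) and Egr1 (0.24 ± 0.12) did not pass either. Nppa and Nppb had control means of 13.75 and 13.20 log2, in the upper part of the range of the control arrays, whose highest value was 14.8.

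Of 33 target genes of SRF and YAP and genes of the cytoskeleton, 5 rose with stretch, or 8 adjusted over the list alone. These were the calponin gene Cnn1 (1.45 ± 0.13), the matricellular genes Ccn1 (1.32 ± 0.16) and Ccn2 (0.81 ± 0.11), the actinin gene Actn1 (0.97 ± 0.13) and the tubulin gene Tubb6 (0.87 ± 0.12). The list median was 0.17, with camera adjusted p = 3.47e-07 and adjusted p = 0.4 with an estimated correlation. Of 21 immediate early genes, which respond first to many stimuli, Fosl1 (1.21 ± 0.08), Atf3 (1.05 ± 0.11) and Myc (0.90 ± 0.11) rose, or 6 adjusted over the list alone. The median was 0.20, with camera adjusted p = 1.62e-11 and adjusted p = 0.181 with an estimated correlation. Of 35 growth factors, Gdf15, Bdnf (0.86 ± 0.09) and Hbegf (0.73 ± 0.10) rose, or 9 adjusted over the list alone, with a list median of 0.055 and camera adjusted p = 2.97e-05 and adjusted p = 0.211 with an estimated correlation. Of 20 p53 targets and cell death genes, Tnfrsf12a (1.48 ± 0.12), Plk2 (0.96 ± 0.11) and Sesn2 (0.91 ± 0.10) rose, or 6 up and 1 down adjusted over the list alone. Their list had a median of 0.078 and camera adjusted p = 6.24e-05 and adjusted p = 0.231 with an estimated correlation. The phosphatase gene Dusp2 (0.87 ± 0.08) rose among 16 feedback genes of MAP kinases (1 adjusted over the list alone; median 0.17; camera adjusted p = 3.84e-05 and adjusted p = 0.231 with an estimated correlation). With 1 array omitted, the median of growth factors was 0.033 without control replicate 2 and 0.036 without stretch replicate 1. That of p53 and cell death genes was 0.171 without control replicate 1 and 0.171 without stretch replicate 2.

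In several lists with a shift under stretch, few or no members passed over all probe sets. All 29 genes of ribosome biogenesis had a change above 0, and 0 of 29 passed in limma (16 at an unadjusted p under 0.05, 14 up and 0 down adjusted over the list alone). The median was 0.32, with camera adjusted p = 2.94e-17 and adjusted p = 0.213 with an estimated correlation. Gnl3 had the largest value (0.70 ± 0.13). Among ribosomal protein genes 0 of 20 passed in limma (0 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone). Their median was 0.14, with camera adjusted p = 0.000558 and adjusted p = 0.59 with an estimated correlation and Rpl4 at 0.28 ± 0.13. In glycolysis 0 of 20 passed in limma (6 at an unadjusted p under 0.05, 2 up and 0 down adjusted over the list alone). The median was 0.18, with camera adjusted p = 0.000221 and adjusted p = 0.239 with an estimated correlation, and with the lactate transporter gene Slc16a3 at 1.04 ± 0.16. In the hypoxia response 1 of 20 rose, Egln3 (0.78 ± 0.11), with 3 up and 1 down adjusted over the list alone and a median of 0.15 (camera adjusted p = 0.000221 and adjusted p = 0.433 with an estimated correlation). In cholesterol synthesis 0 of 19 passed in limma (8 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone). All 19 members had a change above 0, with a median of 0.23, camera adjusted p = 1.22e-06 and adjusted p = 0.297 with an estimated correlation, and Idi1 at 0.63 ± 0.21. In fatty acid oxidation 0 of 28 passed in limma (1 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone). The median was -0.085, with camera adjusted p = 0.000199 and adjusted p = 0.55 with an estimated correlation, and Pdk4 at -0.47 ± 0.14. In the adrenergic and G protein list 0 of 28 passed in limma (4 at an unadjusted p under 0.05, 0 up and 1 down adjusted over the list alone). The median was -0.026, with camera adjusted p = 0.0291 and adjusted p = 0.231 with an estimated correlation, and the angiotensin receptor gene Agtr1a at -0.64 ± 0.10. With 1 array left out, which ended some camera calls, the median of ribosomal proteins was 0.225 without control replicate 1, 0.046 without control replicate 2 (adjusted p = 0.444), 0.205 without stretch replicate 1 and 0.044 without stretch replicate 2 (adjusted p = 0.469). That of glycolysis was 0.115 without control replicate 2 and 0.087 without stretch replicate 2. That of cholesterol synthesis was 0.146 without stretch replicate 1. That of fatty acid oxidation was -0.046 without control replicate 1 (adjusted p = 0.083) and -0.177 without control replicate 2. That of adrenergic and G protein genes was -0.051 without control replicate 1, -0.023 without control replicate 2 (adjusted p = 0.129), -0.043 without stretch replicate 1 (adjusted p = 0.145) and -0.012 without stretch replicate 2.

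Of 26 genes of inflammation, Lcn2, C3 and Cxcl2 fell with stretch and 0 rose, against 7 down and 2 up adjusted over the list alone. The median was -0.11, with camera adjusted p = 5.32e-05 and adjusted p = 0.181 with an estimated correlation. Of fibroblast markers in the same arrays 0 of 18 passed in limma (5 at an unadjusted p under 0.05, 0 up and 1 down adjusted over the list alone), and 3 had a change above 0. Their median was -0.19, with camera adjusted p = 1.22e-06 and adjusted p = 0.181 with an estimated correlation, and Dpt at -0.56 ± 0.10. Of endothelial markers 0 of 13 passed in limma (2 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone), and their median was -0.08, with camera adjusted p = 0.00113 and adjusted p = 0.181 with an estimated correlation and Ecscr at -0.34 ± 0.11. Of extracellular matrix genes 0 of 28 passed in limma (6 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone), and their median was -0.15, with camera adjusted p = 7.2e-05 and adjusted p = 0.231 with an estimated correlation and Timp1 at 0.63 ± 0.14. Macrophage and leukocyte markers had a median of -0.027 (camera adjusted p = 0.463; Lgals3 0.27 ± 0.12). With 1 array omitted, the median of the inflammation list was -0.063 without stretch replicate 2.

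The remaining lists had camera adjusted p-values above 0.05 for stretch. Over all 13 lists without a call, 1 membership rose and 0 fell, against 6 and 1 adjusted over the list alone. Among 12 smooth muscle and pericyte markers Cnn1 rose, and the median was 0.029 (adjusted p = 0.0511). The medians were 0.041 for adult heart genes (Ckmt2 0.51 ± 0.15), 0.035 for the sarcomere (Pdlim5 0.43 ± 0.10), 0.028 for oxidative phosphorylation (Cox7a1 0.17 ± 0.21), 0.044 for the TCA cycle (Pdhx 0.19 ± 0.14) and 0.018 for the cell cycle (Bub1 0.47 ± 0.09). They were -0.028 for red blood cells (Hbb -0.21 ± 0.09), -0.002 for Schwann cells and neurons (Mbp -0.14 ± 0.10) and -0.12 for atrial myocytes. Mesothelial markers (median -0.044, mean 0.009; Krt18 0.30 ± 0.09) and ventricular myocyte markers (median 0.009, mean -0.057; Irx4 -0.49 ± 0.12) had medians and means of opposite sign.

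The number of stretch calls depended on single arrays and on the model. Without control replicate 1, control replicate 2, stretch replicate 1 or stretch replicate 2, the count was 37, 27, 26 or 47, and 9 of the 19 genes with the largest changes passed in all 6 omissions: Mt2A, Hspa1a, Gdf15, Hmox1, Mllt11, Cks2, Gadd45g, Trib3 and Pla2g2a. Of all 39 named stretch calls 12 did. Quantile normalization of the arrays gave 386 changed probe sets, of which 280 rose and 106 fell, so the share of rises was 72.5% in place of 88.8%. A term for the replicate number gave 1028, including all 107 of the main fit, and 69.9% of them rose. The labels do not say whether equal numbers belong together.

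Phenylephrine against control was the comparison for the chemical growth stimulus. Wfdc1, a secreted protease inhibitor-like protein (probe set 1387873_at), rose 7.09-fold (2.83 ± 0.17 log2, SE; adjusted p = 0.00103). Inha, the α subunit of inhibin (probe set 1387124_at), rose 6.26-fold (2.65 ± 0.15; adjusted p = 0.00103), and Cnn1 rose 5.85-fold (2.55 ± 0.13; adjusted p = 0.000968). Eno3, the muscle form of the glycolytic enzyme enolase (probe set 1386907_at), rose 5.76-fold, from 9.97 ± 0.00 to 12.49 ± 0.13 log2 (mean ± SD, n = 2; adjusted p = 0.000968). The lactate transporter gene Slc16a3 rose 5.11-fold (2.35 ± 0.16; adjusted p = 0.00118). Reg3b, a secreted lectin (probe set 1368238_at), fell 3.36-fold (-1.75 ± 0.10; adjusted p = 0.00103).

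Further large rises with phenylephrine were those of the nuclear receptor gene Nr4a3 (2.15 ± 0.12), Asns (1.93 ± 0.15), Nap1l5 (1.80 ± 0.13), Rgs2, which turns off Gq proteins (1.80 ± 0.13), and the laminin gene Lamb3 (1.80 ± 0.11). The largest falls also held Galnt13 (-1.86 ± 0.28), the phosphatase gene Ptprr (-1.56 ± 0.14), Rab3b (-1.53 ± 0.13), the chemokine gene Cxcl11 (-1.41 ± 0.14) and the GABA receptor gene Gabrb2 (-1.38 ± 0.11). Ctso (-1.37 ± 0.29), Masp1 (-1.33 ± 0.15), Klhl33 (-1.33 ± 0.11) and Adhfe1 (-1.32 ± 0.11) completed this group. In limma 1117 of 31042 probe sets changed, 538 up and 579 down, for 378 named genes up and 365 down. Changes of at least 2-fold made up 174 of these, 111 up and 63 down. A fit with a term for the replicate number called 5384, of which 40% rose. The fit of the control and phenylephrine arrays alone called 661.

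Of 16 hypertrophy and fetal genes, 8 rose with phenylephrine and 0 fell, or 12 up adjusted over the list alone. They included Nppa (1.05 ± 0.12; adjusted p = 0.00504), Nppb (1.12 ± 0.12; adjusted p = 0.00418), Acta1 (1.09 ± 0.11; adjusted p = 0.00373), Fhl1 (1.53 ± 0.11) and Timp1 (1.21 ± 0.14). The median was 0.72, with camera adjusted p = 1.91e-12 and adjusted p = 0.249 with an estimated correlation. From the panel, Ccn2 (0.59 ± 0.11) and Fos (1.64 ± 0.21) also rose. Myh7 (0.23 ± 0.11), Myh6 (0.02 ± 0.10), Atp2a2 (-0.01 ± 0.10), Rcan1 (0.33 ± 0.14), Ankrd1 (0.35 ± 0.11), Fgf21 (0.12 ± 0.07), Egr1 (-0.50 ± 0.12), Hmox1 (0.10 ± 0.14) and Gdf15 (0.24 ± 0.10) did not pass. Of 22 sarcomere genes, Pdlim3 (1.04 ± 0.11), Pdlim5 (0.73 ± 0.10), Tcap (0.73 ± 0.12) and Myoz2 (0.52 ± 0.10) rose, with 5 up and 2 down adjusted over the list alone and a median of 0.23 (camera adjusted p = 0.000181 and adjusted p = 0.509 with an estimated correlation). Among 19 adult heart genes the potassium channel subunit gene Kcnip2 fell (-1.30 ± 0.12) and the glucose transporter gene Slc2a4 rose (0.73 ± 0.11), also 1 and 1 adjusted over the list alone, with a median of -0.01 (camera adjusted p = 0.94). With 1 array omitted, the median of sarcomere genes was 0.147 without phenylephrine replicate 2.

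Of 19 genes of cholesterol synthesis, 10 rose with phenylephrine and 0 fell, or 17 up adjusted over the list alone. The examples are Idi1 (1.79 ± 0.21), Acat2 (1.23 ± 0.17), Dhcr7 (1.15 ± 0.11) and Sqle (1.11 ± 0.12). The median was 0.73, with camera adjusted p = 3.44e-17 and adjusted p = 0.249 with an estimated correlation. Of 20 genes of glycolysis, 8 rose and 0 fell, or 10 up and 1 down adjusted over the list alone, among them Eno3, Slc16a3, Pfkl (0.97 ± 0.12) and Tpi1 (0.72 ± 0.11). The median was 0.32, with camera adjusted p = 7.98e-06 and adjusted p = 0.27 with an estimated correlation. Of 28 genes of fatty acid oxidation, 6 fell and 0 rose, or 10 down and 1 up adjusted over the list alone. Pdk4, which restrains pyruvate oxidation, fell by 1.04 ± 0.14, Ech1 by 0.89 ± 0.13, the carnitine transferase gene Cpt1a by 0.70 ± 0.12 and Acaa2 by 0.60 ± 0.13. The median was -0.32, with camera adjusted p = 5.35e-06 and adjusted p = 0.509 with an estimated correlation. Oxidative phosphorylation (median 0.076; camera adjusted p = 0.0612; Cox7a1 0.98 ± 0.21 the only 1 of 38 past the threshold, 0 adjusted over the list alone) and the TCA cycle (median 0.019; adjusted p = 0.532; Pdha1 0.48 ± 0.10 the only 1 of 18) were not called. With 1 array omitted, the median of fatty acid oxidation was -0.203 without control replicate 1 and -0.195 without phenylephrine replicate 2.

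Of 29 genes of the ATF4 response, 13 rose with phenylephrine and 0 fell, or 24 up adjusted over the list alone, including Asns, Mthfd2 (1.70 ± 0.11), the serine synthesis gene Phgdh (1.33 ± 0.12) and Atf5 (1.12 ± 0.13). The median was 0.56, with camera adjusted p = 3.44e-17 and adjusted p = 0.249 with an estimated correlation. Of 18 NRF2 genes 0 rose and 1 fell, Abcc4 (-0.35 ± 0.07), with 7 at an unadjusted p under 0.05, 0 up and 2 down adjusted over the list alone and a median of 0.082 (camera adjusted p = 0.67). Of 16 heat shock genes Hspa1a rose (0.59 ± 0.10), also 1 adjusted over the list alone, and the median was 0.17 (camera adjusted p = 0.0123 and adjusted p = 0.578 with an estimated correlation). In the hypoxia response, 5 of 20 rose, or 11 up and 2 down adjusted over the list alone, such as Egln3 (1.36 ± 0.11), P4ha1 (1.13 ± 0.13) and Bnip3 (0.94 ± 0.14), while Angptl4 fell (-1.03 ± 0.09). The median was 0.32, with camera adjusted p = 8.2e-05 and adjusted p = 0.509 with an estimated correlation. Of 16 feedback genes of MAP kinases 5 rose, or 10 adjusted over the list alone, among them Spry1 (1.09 ± 0.11), Phlda1 (1.03 ± 0.09), Dusp5 (0.75 ± 0.11) and Spry4 (0.58 ± 0.10), with a median of 0.48 (camera adjusted p = 4.6e-09 and adjusted p = 0.249 with an estimated correlation). Of 21 immediate early genes Nr4a3, Fos and Klf4 (0.61 ± 0.11) rose, with 7 up and 1 down adjusted over the list alone and a median of 0.10 (camera adjusted p = 0.00496 and adjusted p = 0.509 with an estimated correlation). When single arrays were omitted, which ended the heat shock call, the median of immediate early genes was 0.026 without control replicate 1, 0.178 without control replicate 2, 0.039 without phenylephrine replicate 1 and 0.223 without phenylephrine replicate 2. That of heat shock genes was 0.116 without control replicate 2 (adjusted p = 0.0907) and 0.066 without phenylephrine replicate 1 (adjusted p = 0.12).

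Of 33 SRF, YAP and cytoskeleton genes 8 rose with phenylephrine, or 16 up and 2 down adjusted over the list alone. Tubb6 (1.27 ± 0.12), Actn4 (0.70 ± 0.11) and Pdlim7 (0.62 ± 0.13) followed Cnn1 in size. The median was 0.35, with camera adjusted p = 3.86e-06 and adjusted p = 0.509 with an estimated correlation. Of 35 growth factors 6 rose, or 8 up and 1 down adjusted over the list alone, among them Areg (1.54 ± 0.12), Tgfb3 (1.52 ± 0.13), Fstl3 (1.43 ± 0.16) and Inhba (0.97 ± 0.13). Their median was 0.068 (camera adjusted p = 0.000429 and adjusted p = 0.27 with an estimated correlation). Among ribosomal protein genes 0 of 20 passed in limma (1 at an unadjusted p under 0.05, 0 up and 0 down adjusted over the list alone). Their median was 0.14, with camera adjusted p = 0.0028 and adjusted p = 0.641 with an estimated correlation and Rpl18 at 0.27 ± 0.11. Of the 15 lists that were not called, 15 memberships rose and 7 fell, against 19 and 17 adjusted over the list alone. In ribosome biogenesis Nhp2 rose (0.58 ± 0.12), with a median of 0.067 (camera adjusted p = 0.0612). Among adrenergic and G protein genes, of which 3 were up and 3 down adjusted over the list alone, 3 rose, such as Rgs2 and the receptor kinase gene Grk5 (0.45 ± 0.09), and 2 fell, the receptor genes Adra1b (-0.73 ± 0.14) and Agtr1a (-0.50 ± 0.10), with a median of -0.052 (adjusted p = 0.569). Among p53 and cell death genes Tnfrsf12a (1.65 ± 0.12), Bnip3 and Plk2 (0.79 ± 0.11) rose and Bcl2l11 fell (-0.73 ± 0.14), with 5 up and 3 down adjusted over the list alone and a median of 0.071 (adjusted p = 0.112). Chaperones of the endoplasmic reticulum had a median of 0.038 (adjusted p = 0.855; Hyou1 -0.42 ± 0.11) and the cell cycle list -0.036 (adjusted p = 0.335; Mcm7 -0.54 ± 0.13). When single arrays were left out, the median of SRF, YAP and cytoskeleton genes was 0.201 without phenylephrine replicate 1. That of growth factors was 0.104 without phenylephrine replicate 1. That of ribosomal proteins was 0.225 without control replicate 1, 0.051 without control replicate 2 (adjusted p = 0.229) and 0.147 without phenylephrine replicate 2 (adjusted p = 0.089).

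Of 26 genes of inflammation 8 fell with phenylephrine and 0 rose, or 9 down and 2 up adjusted over the list alone, including Vcam1 (-0.98 ± 0.13), Cxcl1 (-0.84 ± 0.16), Cxcl10 (-0.84 ± 0.10) and Lcn2 (-0.82 ± 0.12). The median was -0.15, with camera adjusted p = 0.000533 and adjusted p = 0.249 with an estimated correlation. In the same arrays 4 of 18 fibroblast markers fell, or 11 down and 2 up adjusted over the list alone: Dpt (-0.96 ± 0.10), Col3a1 (-0.62 ± 0.11), Postn (-0.58 ± 0.11) and Pdgfra (-0.53 ± 0.10). Their median was -0.31, with camera adjusted p = 1.46e-05 and adjusted p = 0.249 with an estimated correlation. Of 13 endothelial markers Kdr (-0.93 ± 0.12) and Emcn (-0.55 ± 0.07) fell, also 2 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 0.004 and adjusted p = 0.249 with an estimated correlation). In the extracellular matrix list of 28, Timp1 and Vcan (0.89 ± 0.12) rose while Col3a1 and Postn fell, with 4 up and 9 down adjusted over the list alone and a median of -0.21 (camera adjusted p = 0.0265 and adjusted p = 0.509 with an estimated correlation). Of 12 smooth muscle and pericyte markers Cnn1, Cspg4 (1.30 ± 0.10) and Mcam (0.64 ± 0.10) rose and Abcc9 fell (-1.12 ± 0.18), with 5 up and 1 down adjusted over the list alone and a median of 0.069 (camera adjusted p = 0.0417 and adjusted p = 0.359 with an estimated correlation). Some omissions of single arrays ended the calls of the extracellular matrix, smooth muscle and endothelial lists. The median of extracellular matrix genes was then -0.241 without control replicate 2, -0.287 without phenylephrine replicate 1 and -0.209 without stretch replicate 2. That of smooth muscle markers was 0.058 without phenylephrine replicate 1 (adjusted p = 0.051) and 0.081 without phenylephrine replicate 2 (adjusted p = 0.132). That of endothelial markers was -0.096 without phenylephrine replicate 1 (adjusted p = 0.0938).

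The remaining cell type lists were not called for phenylephrine. Macrophage and leukocyte markers had a median of -0.072 (camera adjusted p = 0.111), with Cd68 lower by 0.52 ± 0.11. Krt18 (0.56 ± 0.09) and Krt8 (0.34 ± 0.06) rose among mesothelial markers (median 0.033). Nppa, Myl4 (0.99 ± 0.15) and Fgf12 (0.42 ± 0.08) rose among atrial markers, whose median was -0.015 and whose mean was 0.147. Irx4 fell among ventricular markers (-0.73 ± 0.12; median 0.096). The medians were 0.021 for red blood cells (Hbb -0.07 ± 0.09) and 0.056 for Schwann cells and neurons (Dbh 0.18 ± 0.08).

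Without control replicate 1, control replicate 2, stretch replicate 1 or stretch replicate 2 the phenylephrine count was 263, 189, 659 or 667, and 39 of all 93 named phenylephrine calls passed in all 6 omissions, among them 18 of the 20 genes with the largest changes, not Galnt13 and Ctso. The share of rises was 48.2% with both phenylephrine arrays, 28.9% without replicate 1 (361 up, 888 down) and 71% without replicate 2 (552 up, 226 down), the array with the dim hybridization controls.

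**Figure D2:**
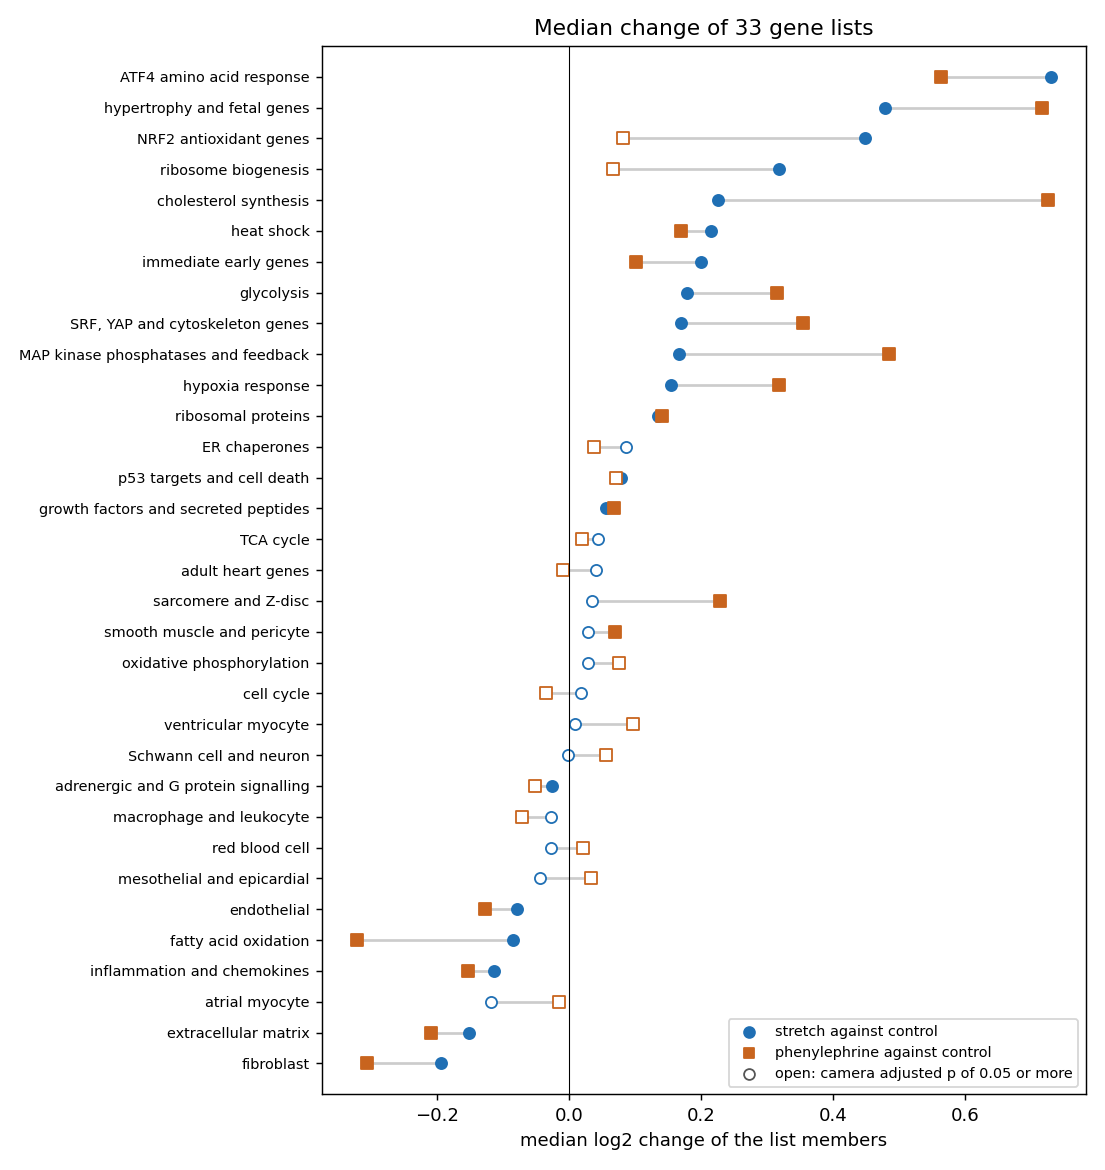
Median log2 change of the members of each of the 33 gene lists with stretch (circles) and with phenylephrine (squares), with filled symbols where the camera adjusted p was below 0.05 with the preset correlation. The ATF4 list had medians of 0.73 with stretch and 0.56 with phenylephrine, and cholesterol synthesis 0.23 and 0.73.

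Stretch was then compared with phenylephrine directly, which also tests whether the changes against control differ. Gdf15 was 6-fold higher in stretched cells (2.59 ± 0.10 log2, SE; adjusted p = 0.000173), Mt2A 5.48-fold (2.45 ± 0.17; adjusted p = 0.00137), Hmox1 5.38-fold (2.43 ± 0.14; adjusted p = 0.000775) and Hspa1a 4.79-fold (2.26 ± 0.10; adjusted p = 0.000258). Wfdc1 was 6.19-fold lower in stretched cells (-2.63 ± 0.17; adjusted p = 0.000926), Inha 5.81-fold (-2.54 ± 0.15; adjusted p = 0.000829) and Eno3 4.81-fold (-2.27 ± 0.12; adjusted p = 0.000683). In limma 413 probe sets differed, 223 higher and 190 lower with stretch, for 159 and 133 named genes. Differences of at least 2-fold made up 95 of these. A fit with a term for the replicate number called 3734, of which 65.3% were higher with stretch.

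The next largest values higher with stretch were those of Cks2 (1.96 ± 0.12), Reg3b (1.91 ± 0.10), Ptprr (1.77 ± 0.14), the chloride channel gene Clic2 (1.67 ± 0.15), Galnt13 (1.63 ± 0.28) and Rab3b (1.52 ± 0.13). Lower with stretch were Nap1l5 (-2.05 ± 0.13), the basement membrane gene Nid2 (-1.68 ± 0.11), the cAMP phosphodiesterase gene Pde4b (-1.63 ± 0.15), Rgs2 (-1.58 ± 0.13), Plppr5 (-1.54 ± 0.12), Nr4a3 (-1.46 ± 0.12) and LOC102554253 (-1.44 ± 0.15). The panel genes Egr1 (0.75 ± 0.12; adjusted p = 0.0313) and Fos (-1.19 ± 0.21; adjusted p = 0.0471) differed in opposite directions. Nppa (-0.32 ± 0.12), Nppb (-0.07 ± 0.12), Acta1 (-0.38 ± 0.11), Ccn2 (0.21 ± 0.11), Myh7 (-0.13 ± 0.11), Myh6 (-0.17 ± 0.10), Atp2a2 (0.04 ± 0.10), Rcan1 (0.14 ± 0.14), Ankrd1 (-0.20 ± 0.11) and Fgf21 (-0.03 ± 0.07) did not pass this test.

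Of 18 NRF2 genes 4 were higher with stretch than with phenylephrine and 0 lower, or 10 higher adjusted over the list alone. These were Hmox1, Srxn1 (1.11 ± 0.12), Osgin1 (0.94 ± 0.12) and the autophagy receptor gene Sqstm1 (0.90 ± 0.10), and the list median was 0.35 (camera adjusted p = 5.07e-10 and adjusted p = 0.655 with an estimated correlation). Of 19 genes of cholesterol synthesis 4 were lower with stretch, or 15 adjusted over the list alone: Idi1 (-1.16 ± 0.21), Sqle (-0.89 ± 0.12), Dhcr7 (-0.87 ± 0.11) and Fdps (-0.78 ± 0.12). The median was -0.50 (camera adjusted p = 1.09e-14 and adjusted p = 0.655 with an estimated correlation). In glycolysis Eno3 and Slc16a3 (-1.31 ± 0.16) were lower, or 6 of 20 adjusted over the list alone (median -0.13; camera adjusted p = 0.000373 and adjusted p = 0.655 with an estimated correlation). In ribosome biogenesis 0 of 29 passed in limma (14 at an unadjusted p under 0.05, 6 higher and 0 lower adjusted over the list alone), with a median of 0.23 (camera adjusted p = 5.28e-06 and adjusted p = 0.677 with an estimated correlation; Gnl3 0.64 ± 0.13). In fatty acid oxidation 0 of 28 passed in limma (9 at an unadjusted p under 0.05, 5 higher and 1 lower adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.00418 and adjusted p = 0.684 with an estimated correlation; Ech1 0.62 ± 0.13). With 1 array omitted, the median of glycolysis was -0.075 without stretch replicate 1. That of fatty acid oxidation was 0.075 without phenylephrine replicate 2 and 0.211 without stretch replicate 2 (adjusted p = 0.0684).

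The other called lists had a downward direction in camera. Among MAP kinase feedback genes Spry1 (-1.06 ± 0.11) and Phlda1 (-0.80 ± 0.09) were lower and Dusp2 higher (0.67 ± 0.08), with 6 lower and 1 higher adjusted over the list alone and a median of -0.26 (camera adjusted p = 9.79e-05 and adjusted p = 0.655 with an estimated correlation). Sarcomere genes had Pdlim3 (-1.39 ± 0.11) and Tcap (-0.70 ± 0.12) lower, with 2 lower and 1 higher adjusted over the list alone and a median of -0.13 (camera adjusted p = 0.000816 and adjusted p = 0.677 with an estimated correlation). Of hypertrophy and fetal genes 0 of 16 passed in limma (8 at an unadjusted p under 0.05, 1 higher and 6 lower adjusted over the list alone), with a median of -0.21 (camera adjusted p = 0.0019 and adjusted p = 0.677 with an estimated correlation; Myl4 -0.62 ± 0.15). In the hypoxia list Angptl4 was higher (0.57 ± 0.09), against a median of -0.18 (camera adjusted p = 0.0192 and adjusted p = 0.684 with an estimated correlation), with 2 lower and 1 higher adjusted over the list alone. Atrial markers had Fgf12 lower (-0.54 ± 0.08), 2 lower adjusted over the list alone, and a median of -0.21 (camera adjusted p = 0.0312 and adjusted p = 0.677 with an estimated correlation). When 1 array was left out, the median of hypertrophy and fetal genes was -0.094 without stretch replicate 1 and -0.318 without stretch replicate 2. That of sarcomere genes was -0.096 without phenylephrine replicate 2 (adjusted p = 0.126), -0.044 without stretch replicate 1 (adjusted p = 0.169) and -0.227 without stretch replicate 2. That of the hypoxia response was -0.079 without phenylephrine replicate 1 (adjusted p = 0.12). That of atrial markers was -0.07 without phenylephrine replicate 1 (adjusted p = 0.235) and -0.125 without stretch replicate 2.

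The ATF4 list was not called between the treatments (median 0.11; camera adjusted p = 0.168), although Gdf15, Trib3 (0.96 ± 0.09), Ddit3 (0.84 ± 0.12) and Cebpb (0.78 ± 0.11) were higher with stretch and 1 member was lower. Immediate early genes went both ways, with 4 higher, among them Myc (0.97 ± 0.11) and Fosl1 (0.92 ± 0.08), and Nr4a3 and Fos lower (median 0.066; adjusted p = 0.193). Of growth factors 2 were higher, among them Gdf15, and 4 were lower, among them Areg (-0.92 ± 0.12), Tgfb3 (-0.86 ± 0.13) and Inhba (-0.79 ± 0.13) (median -0.022; adjusted p = 0.193). Inflammation genes with higher values under stretch were Ccl20 (0.72 ± 0.13) and Cxcl10 (0.67 ± 0.10; list median 0.036; adjusted p = 0.431). Cnn1 (-1.10 ± 0.13), Actn4 (-0.61 ± 0.11), Cspg4 (-0.79 ± 0.10), Mcam (-0.67 ± 0.10), Vcan (-0.78 ± 0.12) and Slc2a4 (-0.64 ± 0.11) were lower with stretch, and Kcnip2 (1.28 ± 0.12), Kdr (0.80 ± 0.12), Bub1 (0.57 ± 0.09) and Gadd45b (0.67 ± 0.11) were higher, in lists that were not called. Fibroblast markers had a median of 0.12 (adjusted p = 0.0621). In all, 23 lists were not called, in which 17 memberships were higher and 15 lower, or 36 and 34 adjusted over the list alone, with medians between -0.11 and 0.121 and a lowest camera adjusted p of 0.0569.

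The matrix and TCA cycle lists had medians of 0.032 and 0.048 but a downward camera direction. Without control replicate 1, control replicate 2, phenylephrine replicate 2, stretch replicate 1 or stretch replicate 2 the count of 413 was 215, 223, 264, 51 or 65, and 21 of all 57 named calls passed in all 6 omissions, among them 18 of the 20 genes with the largest differences, not Galnt13 and LOC102554253. The share higher with stretch was 54%, against 76.3% without phenylephrine replicate 1 and 28% without phenylephrine replicate 2.

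Some probe sets passed in both comparisons with control. Of these 52 rose, for 40 named genes, and 10 fell, while in limma 0 passed in opposite directions (57 at an unadjusted p under 0.05 in both). Genes rising in both included Nppb, Fhl1, Cnn1, Ccn2, Asns, Mthfd2, Trib3, Tnfrsf12a, Mllt11 and Hbegf. Genes falling in both included Pla2g2a, Lcn2, C3, Gja5, Cxcl2 and Epha4. Independent lists of these sizes would share 1.65 rises and 0.22 falls. Part of the excess may come from the shared controls. With separate controls the numbers were 2 rises and 2 falls (stretch against control replicate 1, phenylephrine against control replicate 2) or 9 and 1 (the other way round), in fits with fewer calls, of 23 and 171 or 35 and 110 rises. There independent lists would share 0.127 and 0.00947 or 0.124 and 0.00232. Without control replicate 1 the numbers were 10 and 2, and without control replicate 2 they were 4 and 2. These alternatives were chosen after seeing the data.

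Across the 31042 probe sets, which are not independent replicates, the changes with stretch and with phenylephrine had a Pearson correlation of 0.525. Simulations without any effect, which treat all arrays as independent, gave 0.5 on average, and 0.518 at most in 100 data sets. The covariance was 0.0165 against 0.00529 in the simulations, a difference of 0.0112 under that assumption. With separate controls, which share no array, the correlation was 0.254 or 0.339 and the covariance 0.00958 or 0.0125. Of the 107 probe sets that changed with stretch, 45 also differed between stretch and phenylephrine. Of the 95 rises with stretch, 40 were higher with stretch than with phenylephrine in that test.

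**Figure D3:**
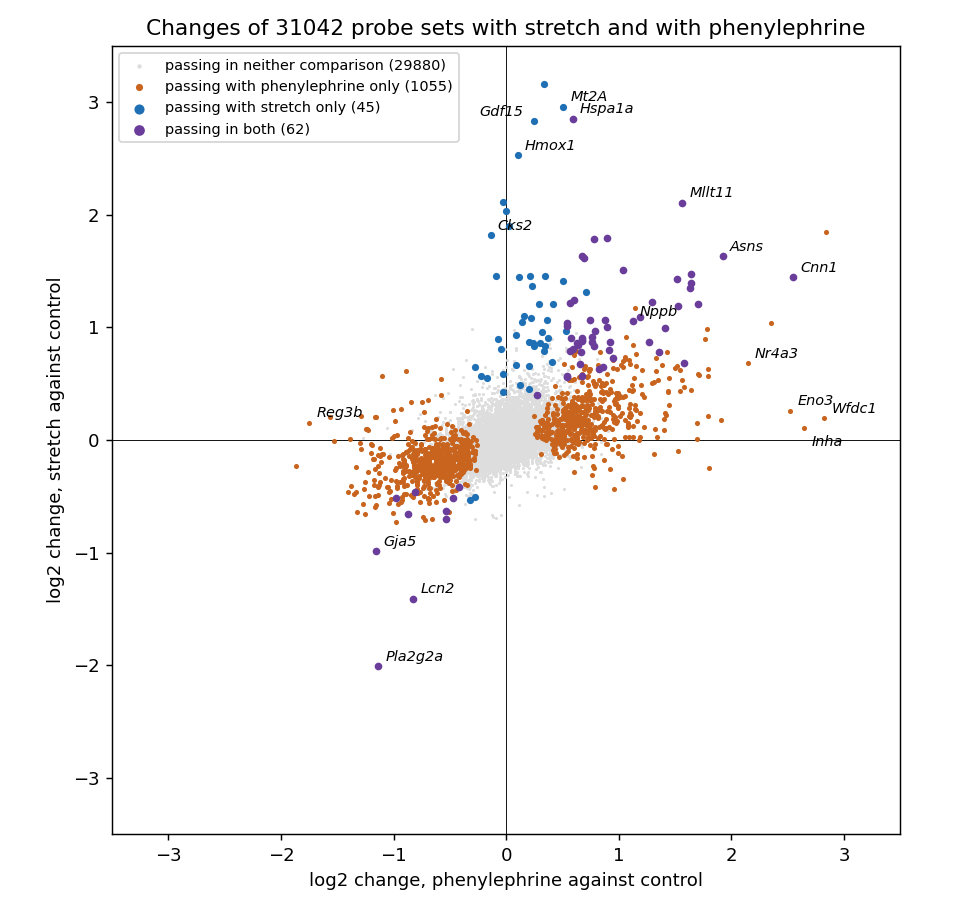
log2 change of each of the 31042 probe sets with phenylephrine (horizontal axis) and with stretch (vertical axis), both against the same 2 control arrays. Colours mark the 62 probe sets past the threshold in both comparisons, the 45 with stretch only, the 1055 with phenylephrine only and the 29880 in neither. Hmox1 and Gdf15 lie near 0 on the horizontal axis (0.10 and 0.24), and Inha and Eno3 near 0 on the vertical axis (0.11 and 0.26).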

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

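The tests of the explanations weighed in this part, on leukocyte markers, single stretch arrays, the growth surface and non-myocyte markers, were chosen only after the results they concern had been seen. For 13 of the named genes, both stretch arrays lay on one side of the controls and both phenylephrine arrays on the other, and the difference between the treatments passed in limma. The stretch minus phenylephrine difference was 1.907 log2 for Reg3b, 1.768 for Ptprr, 1.674 for Clic2, 0.943 for Osgin1, 0.9 for Sqstm1, 0.839 for Ddit3, 0.779 for Cebpb, 0.748 for Egr1 and 0.667 for Gadd45b. It was -2.048 for Nap1l5, -1.439 for LOC102554253, -1.39 for Pdlim3 and -0.535 for Fgf12. None of the 13 passed the test of stretch against control (lowest adjusted p = 0.112, for Ddit3), and 7 passed that of phenylephrine against control.

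Control probe sets outside the 31042 tested were also higher than on both control arrays. The GAPDH 3′ probe set was higher by 0.394 log2 with phenylephrine and by 0.183 with stretch, the beta-actin 3′ probe set by 0.207 with phenylephrine, and the hexokinase 3′ probe set by 0.385 with phenylephrine. These differences were not tested.

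The first pattern weighed is the rise of stress genes with stretch (Mt2A, Hspa1a, Gdf15, Hmox1 and the NRF2 and ATF4 lists, both at adjusted p = 0.181 with an estimated correlation), of which the ATF4 list was also called with phenylephrine (median 0.564, 13 of 29 up) and not between the treatments (camera adjusted p = 0.168). Macrophages or other leukocytes in the stretched cultures would bring their own transcripts, but the median change of their 18 markers was -0.027 with an SD of 0.089 between them, although 15 of them lay above the median signal in controls, Lgals3 highest at 12.9. A single aberrant stretch array is also argued against, since the lowest list median of either stretch array was 0.414 above the control mean. The growth surface stays open: 0 unstretched arrays are labelled as grown on the membrane, so stretch and membrane cannot be told apart. The plating time and the period without serum are given for the stretched cells only, so a difference in these stays open too. The rise may belong to any of them. A biological effect of the stretch itself is a hypothesis that this design leaves untested against the surface and these culture conditions.

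The second pattern is the fall of 10 probe sets with both treatments, those of the inflammatory genes Pla2g2a, Lcn2, C3, Cxcl2 and Cxcl3 and of Abi3bp, Epha4, Gja5, Kif26b and Slc25a34. Fewer fibroblasts or other non-myocytes could lower such genes. With stretch, the lowest median of any non-myocyte list was that of fibroblasts, -0.194, against a smallest fall of -0.415. The SD of the list members was 0.189, and 2 of the 18 markers fell as much. The threshold keeps small falls out of the 10, so this gap cannot decide whether fewer fibroblasts lowered them. The largest fall, -2.008 for Pla2g2a, lay beyond that of the lowest marker, -0.564. With phenylephrine the fibroblast median was -0.306 against a smallest fall of -0.42, with an SD of 0.326 and 6 of 18 markers as low, so fewer fibroblasts and a change of expression cannot be told apart. Of the 18 markers 6 are also in another list, 17 lay above the median signal in controls, and S100a4 was brightest at 14.1; the cells had been separated from fibroblasts on Percoll.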

How the results depend on the processing

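Alternatives for the overlap of both treatments, and the separate controls, were chosen after seeing the data, and all others before. Of 189 named-gene calls and 48 list calls, 0 turned in direction in limma, camera or fry under the alternatives. All alternatives reuse the same arrays and the calls were selected for their change, so few reversals could occur. Of 67 named-gene values without a call, 79 of 934 tests under the alternatives passed, 0 of them in the other direction. The balance of calls did turn. Between stretch and phenylephrine it went from 54% higher with stretch to 48.3% with quantile normalization and 28% without phenylephrine replicate 2. The share of rises with phenylephrine went from 48.2% to 53.4% with the 2 groups alone, 62% and 59.3% without control replicates 1 and 2, 53.4% and 53.2% without stretch replicates 1 and 2, and 71% without phenylephrine replicate 2. The counts of changed probe sets (107, 1117 and 413 for stretch against control, phenylephrine against control and stretch against phenylephrine) became 386, 2790 and 1527 with quantile normalization, which called 107, 1115 and 413 of the same probe sets. The cause was not tested. With the 2 groups alone they were 112, 661 and 230, and the cause was not tested. The 2 phenylephrine arrays differed more from each other (median absolute difference 0.119 log2) than the controls (0.077) or the stretch arrays (0.081). The main fit shares 1 spread over all 3 groups, so its SE may be too small in comparisons with phenylephrine. At least 2-fold changes numbered 48, 174 and 95, and an adjusted p under 0.10 gave 169, 1901 and 789. Omitting 1 array gave 26 to 112, 189 to 1249, and 51 to 473. The lone array left in a group is then assumed to vary like the other groups. Of 33 gene lists 0, 0 and 0 were called by camera with an estimated correlation (7, 6 and 0 at an unadjusted p under 0.05), and 12, 10 and 0 by fry. Of the 48 list calls, quantile normalization ended 5, the filter on dim probe sets 3, and the term for the replicate number 3. The mean of a gene's probe sets ended 2. The correlation of both changes ran from 0.439 to 0.622 when 1 array was omitted, and was 0.254 or 0.339 with separate controls. Of 189 named-gene calls, 72 held in every setting.

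With a replicate block for the replicate number, 1028, 5384 and 3734 probe sets were called, including all 107, 1117 and 413, and 69.9%, 40% and 65.3% of them rose, against 88.8%, 48.2% and 54% without it. The labels do not say that equal numbers share a preparation. Deviations of equally numbered arrays correlated at 0.487 for control and phenylephrine, 0.673 for control and stretch, and 0.534 for phenylephrine and stretch. The median absolute difference was 0.069 log2 between control and stretch replicates 1 and 0.072 between their replicates 2, against 0.077 between the controls. Phenylephrine replicate 1 lay at 0.082 from stretch replicate 1, and phenylephrine replicate 2 at 0.103 from stretch replicate 2, against 0.119 between the phenylephrine arrays. Control and phenylephrine arrays of equal number lay at 0.087 and 0.113. These values come from the data and not from the design. The main fit counts deviations shared by equal numbers as spread. If equal numbers share deviations, these cancel between whole groups, so that the simulated covariance without any effect, 0.00529, is too high, and they enter the fits with separate controls in opposite directions, which lowers the correlations of 0.254 and 0.339. Probe sets rising and falling in both treatments numbered 398 and 250 with the block, and 60 and 8 without phenylephrine replicate 2. Dim and very bright probe sets limit the size of changes. A robust spread for lists was not run.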

Other observations

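The genes in this part were chosen after their values were seen, and the 9 tests of 3 further lists were chosen only after the gene results that prompted them, before the values of those lists were seen. Among genes outside the lists that rose with stretch in limma were Cenpn, a centromere protein gene (0.93 ± 0.09 log2, SE, n = 2 arrays per group; adjusted p = 0.00678), the kinesin gene Kif20b (0.81 ± 0.10) and the condensin gene Smc4 (0.57 ± 0.08). They were not tested as a group. The cell cycle list, fixed beforehand, was not called (0.018 median; camera adjusted p = 0.174). In it 0 of 30 passed in limma (4 at an unadjusted p under 0.05, 3 up and 0 down adjusted over the list alone).

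Single genes outside the lists that fell with phenylephrine included the fatty acid binding protein gene Fabp4 (-1.20 ± 0.14; adjusted p = 0.00552), the kinase gene Pdk2 (-1.17 ± 0.14) and the lipid droplet genes Plin4 (-1.12 ± 0.13) and Plin5 (-0.95 ± 0.09). Bmp7 (1.41 ± 0.09), Id4 (1.35 ± 0.16), Id1 (0.84 ± 0.12) and Bambi (0.96 ± 0.11) were among those that rose. No group test was run on these genes.

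Because Pde4b, Nr4a3 and Sik1 (1.58 ± 0.10) rose with phenylephrine, 12 further target genes of the transcription factor CREB were tested. Their median was 0.175 with camera adjusted p = 0.00111, fry adjusted p = 0.0136 and adjusted p = 0.108 with an estimated correlation, over 9 tests of the 3 lists. Only Stc1 rose (0.88 ± 0.11; adjusted p = 0.00699). With stretch the list median was 0.072 (camera adjusted p = 0.00237, fry adjusted p = 0.0389, adjusted p = 0.108 with an estimated correlation), and 0 passed in limma, with 2 at an unadjusted p under 0.05. Between the treatments it was -0.068 (camera adjusted p = 0.218, fry adjusted p = 0.0642). A small shift of CREB targets is a hypothesis that may hold for phenylephrine, and is not shown to be particular to it.

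The falls of Cxcl10 and Cxcl11 led to a test of 22 interferon-stimulated genes. With phenylephrine 10 fell and 0 rose, for example Usp18 (-0.93 ± 0.09), Irf7 (-0.91 ± 0.10) and Isg15 (-0.83 ± 0.09). The median was -0.352, with camera adjusted p = 4.37e-11, fry adjusted p = 0.0136 and adjusted p = 0.108 with an estimated correlation. With stretch the median was -0.178 and 0 passed in limma, with 9 at an unadjusted p under 0.05 (camera adjusted p = 1.24e-10, adjusted p = 0.108 with an estimated correlation, fry adjusted p = 0.0444). Between stretch and phenylephrine the median was 0.148, with 1 gene higher with stretch (camera adjusted p = 0.000104, fry adjusted p = 0.0444, adjusted p = 0.249 with an estimated correlation). In the same phenylephrine arrays fibroblast markers had a median of -0.306, with 4 of 18 lower, and the endothelial genes Kdr (-0.93 ± 0.12) and Emcn (-0.55 ± 0.07) fell. Whether fewer such cells account for the interferon genes was not tested. Lower interferon-driven transcription, in myocytes or in other cells of the culture, is a candidate explanation.

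The falls of Reg3b, Lcn2 and Hamp (-1.29 ± 0.14) with phenylephrine raised the hypothesis of lower STAT3 activity. Of 21 further STAT3 and acute phase genes 0 fell and 1 rose in limma, with 1 up and 2 down at an unadjusted p under 0.05. The gene that rose was Lbp (0.54 ± 0.09), and the median was -0.005 (camera adjusted p = 0.979). The outcome set beforehand as counting against the hypothesis, a median near 0 without a downward call, was met. Only 9 of the 21 lay above the median signal in controls, with a median of -0.081, and dim members have little room to fall. In the interferon list 10 of 22 lay above that signal, and 10 members fell with phenylephrine. The brighter 10 had a median of -0.524, against -0.352 for all 22. That list therefore does not show that dim members could have revealed a fall. The STAT3 list as measured showed no broad fall. With only 9 of 21 members above the median signal, it cannot decide whether STAT3 activity was lower.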
